A study of Mus musculus with 3 samples.

How the data were processed

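Total RNA from mouse epididymis (100 μg per sample) was separated on a 15% denaturing gel, the 15 to 50 nt range was excised, and libraries were made with a commercial small RNA kit, per the labels' protocols. The size selection removes intact tRNA, so the reads describe fragments, and small shifts of the excised window would change class shares and fragment lengths. Tables of 3 kinds were deposited. The first gives raw read counts of 5 RNA classes (rRNA, tRNA, snoRNA, miRNA and mRNA), and the second raw read counts of 446 nuclear tRNA genes, both as deposited by the authors. The third kind, 1 sheet per library, gives for each tRNA gene its coordinates and the reads at each fragment length in 2 unnamed end classes. Adapter trimming software (cutadapt) and the mouse build mm10 are named in the submitters' processing notes, without versions or roles. The aligner, the counting tool, the tRNA annotation and the treatment of reads that match several genes are not given in the sources used here. The 10 abundant Gly-GCC copies carry near-equal counts (262347 to 299456 wild type reads), as when shared reads are spread over copies, while in Asn-GTT and Gly-CCC 1 copy stands above the others. Ligation-based libraries also read poorly through some tRNA modifications, and with this design a change in modification and a change in fragment amount give the same kind of count difference.

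The tRNA gene counts summed to 59.4%, 59.4% and 59.1% of the tRNA class row in the wild type library and in Alkbh3-/- libraries A and B, and the fragment sheets to 95.5%, 94.1% and 94.2%. The reason for this gap is not stated. The class table has no total, so the sum of its 5 rows served as library size, 15107055, 15411457 and 21169908 reads. The fragment sheets hold no sequences, so a fragment was defined by isoacceptor, length and end class, and genes without reads are left out of them. The lengths reached beyond 50 nt and were kept. Of 413 genes with coordinates, 368 had the same chromosome, start and end as a tRNA of RefSeq GRCm38.p6, the assembly of mm10, and gene context was taken from GENCODE M21. In the sheets, 6 columns that give the sums of the end classes were not used. Columns were assigned to genotypes by their names. The wild type name begins with B6, which may be a strain label, and the Alkbh3-/- names carry no such prefix. Whether the groups share a genetic background is therefore not known here. The 2 Alkbh3-/- libraries differed by more than sampling noise (chi-square per degree of freedom 272 over isoacceptors, with reads taken as independent), so they were not counted as 1 library deposited in duplicate. This does not show that they came from separate animals.

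Counts were summed per isoacceptor, and those with 10 or more reads over the 3 libraries were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with no composition factor and Benjamini-Hochberg adjustment. The model had 1 residual degree of freedom. Its estimated prior degrees of freedom were infinite for isoacceptors and fragments, and 1.73 for isoacceptors with TMM scaling. Where they were infinite, the spread was pooled over features and not taken from each one, at a level that still differed between features. The model's spread came from the 2 Alkbh3-/- libraries alone, and the lone wild type library was assumed to vary like them. SE is the size of the log2 fold change divided by the square root of its F statistic. Fragments with 10 or more reads in each library were tested in the same way. Lists of tRNAs were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Of the lists drawn up, the mitochondrial one matched 0 genes of the table, and 5 miRNA lists were not used here because the class table holds a miRNA total and no single miRNAs. Class and length shares carry exact Clopper-Pearson 95% intervals, which cover counting error only because PCR copies are not independent molecules.

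The groups, tests, lists and most alternatives were fixed before the data were examined. So was the naming rule. It takes the 10 isoacceptors with the highest mean RPM, plus the 5 largest rises and 5 largest falls among those with a mean of 50 or more reads and the same direction in both Alkbh3-/- libraries, and likewise for fragments. Alternatives tried were TMM scaling, library sizes from the tRNA sums, DESeq2 1.42.0, other count filters, single genes, and each Alkbh3-/- library left out. Added after seeing the data were the class denominators without miRNA or rRNA, other tables for the tRNA share, isoacceptor sums from the fragment tables, the fragment tables' own sums, edgeR's older quasi-likelihood method, and removal of 2 gene copies. The tests were tried on 20 simulated datasets per comparison. For isoacceptors (46 features, 12 changed) edgeR recovered 46.7% of 2-fold and 89.2% of 4-fold changes, with 7.43% of calls false. DESeq2, counted without regard to direction, recovered 63.3% and 95.8% of them, with 8.21% false, so its fewer calls in the data are not explained by lower recovery in these simulations. For fragments (572 features, 200 changed) edgeR recovered 10.5% and 53.4%, with 2.81% false, and DESeq2 8.95% and 53.2%, with 2.28% false. The camera test found a shifted list of 8 in 20 of 20 datasets and called an unshifted one in 1, at an unadjusted p under 0.05. All simulated libraries, wild type included, were drawn with 1 dispersion common to all isoacceptors or all fragments, estimated from the Alkbh3-/- libraries. Features were drawn independently. Rises and falls were equal in number, and the library sizes given to edgeR were the true ones. The rates therefore do not cover unequal spread between features, a wild type library that varies otherwise, or a shift from scaling. The false share also depends on the share of features changed, 200 of 572 simulated fragments against 13 called in the data, so it is not the error rate of those calls. Figures were drawn with matplotlib 3.10.9.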

Results

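Small RNA of 15 to 50 nt was sequenced from the epididymis, the duct in which mouse sperm mature, of wild type mice and of mice lacking Alkbh3. ALKBH3 is a demethylase that removes methyl groups from adenosine and cytidine in nucleic acids, tRNA included. The series holds 3 libraries, 1 from wild type and 2 from Alkbh3-/- tissue. The Alkbh3-/- libraries are called A and B here, in the order of the deposited columns, whose names cannot be tied to the replicate numbers of the labels. Reads assigned to 5 RNA classes came to 15107055 in the wild type library, 15411457 in library A and 21169908 in library B. The labels do not say whether the 2 Alkbh3-/- libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Alkbh3 itself was not analysed here, so the genotype labels were not checked against the RNA.

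The first comparison asked how the small RNA was divided among RNA classes in each genotype. microRNA, the class of short regulatory RNAs that guide Argonaute proteins, made up 15.1% of the reads in the wild type library and 27.8% ± 4.17 (SD, n = 2) in the Alkbh3-/- libraries, a ratio of 1.84. tRNA-derived reads made up 44.7% in wild type and 37.3% ± 1.13 (SD, n = 2) in Alkbh3-/-. For each tRNA-class read the wild type library held 0.337 miRNA reads, library A held 0.680 and library B held 0.807. For both classes the Alkbh3-/- libraries lay on the same side of wild type, and the nearer one was farther from it than the 2 were from each other. The nearer miRNA share lay 9.76 percentage points from wild type against a gap of 5.90 points between the Alkbh3-/- libraries, and the nearer tRNA share 6.62 points against a gap of 1.60.

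Ribosomal RNA took 29.3% of the wild type reads and 25.7% ± 3.24 (SD, n = 2) of the Alkbh3-/- reads. For snoRNA, which guides modification of ribosomal RNA, the shares were 2.97% and 2.41% ± 0.397 (SD, n = 2). For mRNA they were 7.95% and 6.86% ± 2.46 (SD, n = 2). In these 3 classes the nearer Alkbh3-/- library was closer to wild type than to the other Alkbh3-/- library. Exact Clopper-Pearson 95% intervals were narrow at this depth, 44.69 to 44.74% for the wild type tRNA share, and they cover counting error only. No test was made on the shares, since 1 library against 2 allows no exact permutation p below 0.33. The pattern seen for miRNA and tRNA has that same probability, 0.33, in any class if the 3 libraries are exchangeable. The shares are also parts of a common total, so the classes are not independent. With miRNA left out of the total, the tRNA shares were 52.6% in wild type, 48.5% in library A and 55.0% in library B, so on that base the share was lower in library A and higher in library B.

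**Figure D1:**
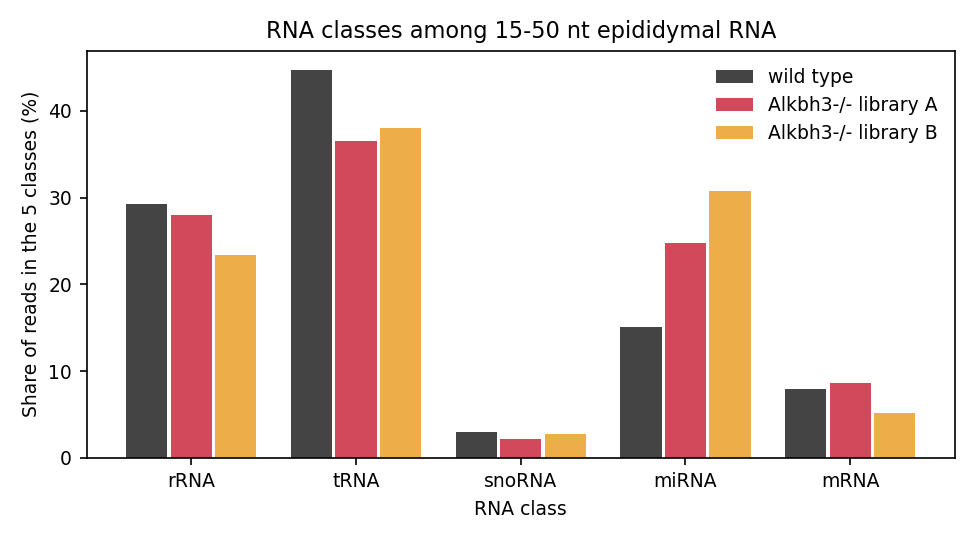
Share of reads in each of 5 RNA classes (percent, linear axis from 0) for the wild type library and the 2 Alkbh3-/- libraries, 1 bar per library. The miRNA bars stand at 15.1% for wild type and at 24.8% and 30.7% for Alkbh3-/-, and the tRNA bars at 44.7% against 36.5% and 38.1%.

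The second comparison asked which tRNAs supplied the reads in each genotype. Reads were summed over gene copies of each isoacceptor, the set of tRNAs with one amino acid and one anticodon, and are given as RPM, the reads scaled to an equal sum of the 5 classes in each library. Gly-GCC, the most abundant source in all 3 libraries, fell from 189621 RPM in wild type to 130384 ± 3381 RPM (SD, n = 2) in Alkbh3-/-, a log2 fold change of -0.54 (SE 0.05, edgeR quasi-likelihood adjusted p = 2.2e-12). Glu-CTC rose from 30918 to 56010 ± 2113 RPM (SD, n = 2), a log2 fold change of 0.86 (SE 0.13, edgeR adjusted p = 1.0e-06). Gly-GCC accounted for 71.4% of the tRNA gene counts in wild type and 59.0% on average in Alkbh3-/-, and Glu-CTC for 11.6% and 25.3%. The ratio of Gly-GCC to Glu-CTC reads, which needs no scaling, was 6.13 in wild type and 2.33 ± 0.0275 (SD, n = 2) in Alkbh3-/-.

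Of 46 isoacceptors tested, 11 passed an edgeR adjusted p of 0.05, with 3 higher and 8 lower in Alkbh3-/-. The deepest fall was that of Asn-GTT, from 209.6 to 55.2 ± 13.7 RPM (SD, n = 2), a log2 fold change of -1.89 (SE 0.33, edgeR adjusted p = 1.2e-05). Thr-AGT fell by 1.28 on the log2 scale (SE 0.18, edgeR adjusted p = 2.5e-07), Arg-TCG by 0.96 (SE 0.26, adjusted p = 0.0051) and Ile-AAT by 0.80 (SE 0.19, adjusted p = 0.0013). Ser-AGA rose with a log2 fold change of 0.62 (SE 0.21, edgeR adjusted p = 0.022), and Leu-CAG with 0.55 (SE 0.21, adjusted p = 0.044). Trp-CCA, Gln-TTG and Arg-CCG, named after their values were seen, also fell, with log2 fold changes of -0.75, -0.64 and -0.60.

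The other abundant isoacceptors did not pass the main test. Gly-CCC had a log2 fold change of -0.61 (SE 0.26), His-GTG -0.68 (SE 0.53), Val-CAC -0.37 (SE 0.49) and Glu-TTC 0.64 (SE 0.68). In 1 other setting each, Glu-TTC passed with DESeq2 (0.93, adjusted p = 0.019) and Gly-CCC with the tRNA sums as library sizes (-0.35, edgeR adjusted p = 0.0050). Ala-CGC had 0.37 (SE 0.69). These SEs rest on the pooled spread, so they do not show how far the 2 Alkbh3-/- libraries differed. In libraries A and B the log2 ratios were -0.64 and -0.59 for Gly-CCC, -0.45 and -0.87 for His-GTG and -0.63 and -0.21 for Val-CAC. For Glu-TTC they were 0.48 and 0.74, and for Ala-CGC 0.29 and 0.43. Values for Lys-CTT, Val-AAC and Asp-GTC were -0.16, -0.26 and -0.08, each smaller than its SE, and each turned positive under at least 1 other scaling. Among those with the largest differences, Leu-TAA (0.75, SE 0.37) and Val-TAC (-0.80, SE 0.41) also missed the threshold. Leu-TAA passed in 3 of 9 settings, with edgeR adjusted p = 0.014 for TMM, 0.0050 for the tRNA sums and 0.017 for the fragment tables.

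The tRNA genes lie in mm10 as the deposited tables place them. Of the gene copies with the most reads, Gly-GCC-2-7 is on chromosome 13 at 21710580 to 21710650 on the plus strand, and Glu-CTC-1-7 on chromosome 10 at 30811140 to 30811211 on the plus strand. Asn-GTT-3-2 is on chromosome 2 at 18587044 to 18587117 on the minus strand, Thr-AGT-1-3 on chromosome 11 at 69062744 to 69062817 on the minus strand, and Gly-CCC-5-1 on chromosome 3 at 96311254 to 96311324 on the plus strand. All 5 lie between genes of the GENCODE M21 annotation, whereas Lys-CTT-3-3, on chromosome 11 at 48833883 to 48833955 on the minus strand, lies in an intron of Trim7. Near-identical copies may share reads, so values of single copies are uncertain. Asn-GTT-3-2 alone held 1133 of the 3167 wild type Asn-GTT reads, and without it Asn-GTT still fell, by 1.57 on the log2 scale (SE 0.36, edgeR adjusted p = 0.0012). In the fragment tables this copy did not stand out, with 138 of 1526 wild type reads against 179 for Asn-GTT-3-3. Gly-CCC-5-1 held 97.7% of the wild type Gly-CCC reads, at a level within the range of the 10 abundant Gly-GCC copies, and without it the Gly-CCC log2 fold change was 0.05 (SE 0.56).

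The isoacceptor calls depended on the scaling and the test. The median log2 fold change of all tested isoacceptors was -0.26 as scaled here and 0.01 with the sums of the tRNA counts as library sizes. Relative to the median of -0.26, Glu-CTC stood at 1.12, Gly-GCC at -0.28 and Asn-GTT at -1.63. Scaling by the tRNA sums gave 4 higher and 5 lower, and DESeq2 2 higher and 1 lower. Glu-CTC passed in 9 of 9 settings that used isoacceptors, and Gly-GCC, Asn-GTT, Thr-AGT and Arg-TCG in 8 each, while Trp-CCA and Arg-CCG passed in 5, Gln-TTG, Ser-AGA and Leu-CAG in 4 and Ile-AAT in 3. The spread was pooled over isoacceptors (infinite prior degrees of freedom), so the small p-values do not rest on each isoacceptor's own spread. The pooled level still differed between isoacceptors, with an SE of 0.05 for Gly-GCC and 0.74 for Asp-GTC. Passing therefore depended on that level as well as on the change. Gly-CCC, at log2 ratios of -0.64 in library A and -0.59 in library B, did not pass, while Gly-GCC, at -0.57 and -0.51, did. With TMM scaling, where the prior was 1.73 degrees of freedom, the edgeR adjusted p was 0.019 for Gly-GCC, 0.013 for Glu-CTC and 0.023 for Asn-GTT. DESeq2 gave Gly-GCC a log2 fold change of -0.22 (adjusted p = 0.69), Thr-AGT -0.97 (adjusted p = 0.057) and Arg-TCG -0.63 (adjusted p = 0.37), and reads taken from the fragment tables gave Asn-GTT -1.16 (edgeR adjusted p = 0.11).

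**Figure D2:**
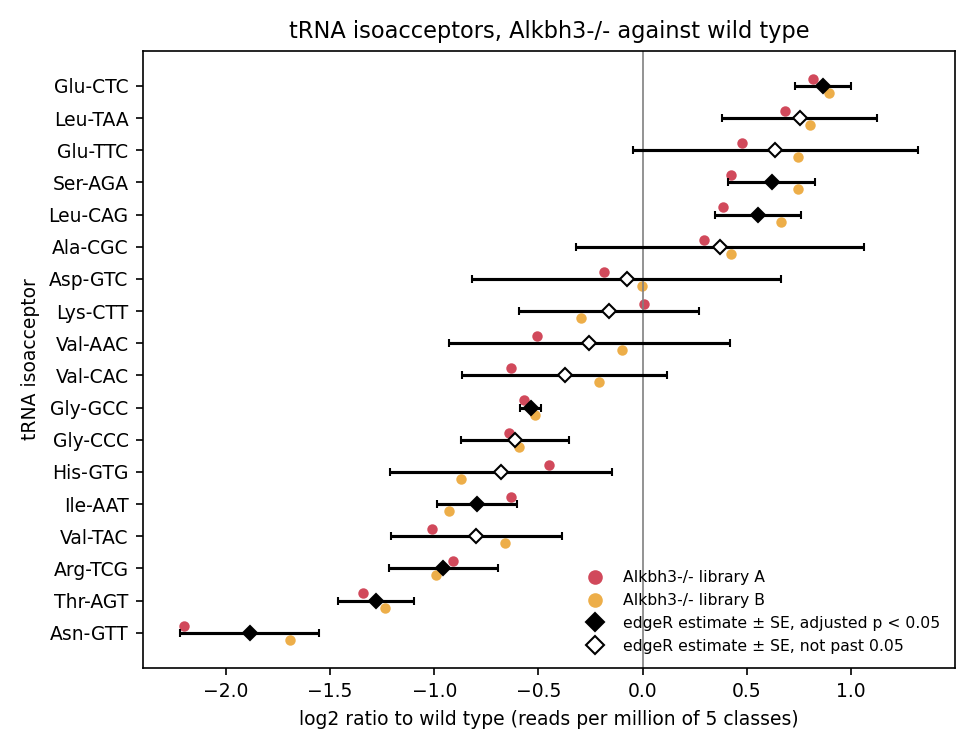
log2 ratio of RPM in Alkbh3-/- to wild type for the 18 named isoacceptors. Circles are the 2 Alkbh3-/- libraries, diamonds the edgeR estimates with bars of 1 SE, and filled diamonds those with an adjusted p under 0.05, from Glu-CTC at 0.86 to Asn-GTT at -1.89.

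Of 8 leucine and serine tRNAs tested, which have a long variable arm, 2 rose (Ser-AGA and Leu-CAG) and 6 did not pass, with a median log2 fold change of 0.43 and values above 0 in both libraries for 7 of the 8. Set against the other isoacceptors, whose changes centred below 0, the list passed camera at its preset correlation (adjusted p = 0.0011). At that correlation it also passed with TMM scaling (camera adjusted p = 0.00029). With an estimated correlation it did not pass (camera adjusted p = 0.776). That estimate was -0.071, below the preset, and the test then rests on the 1 residual degree of freedom, so few lists could pass. The tRNAs known to carry 3-methylcytidine, a mark that ALKBH3 can remove, moved in both directions. Of 9 tested, Ser-AGA and Leu-CAG rose, Thr-AGT fell and 6 did not pass. The median of this list was 0.24 and its mean -0.04, so they differed in sign, and camera gave adjusted p = 0.480 with the direction up. Ser-AGA and Leu-CAG belong to both lists.

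Of 4 glycine tRNAs, Gly-GCC fell and 3 did not pass (camera adjusted p = 0.480). Adjusted over the list alone, 2 glycine tRNAs were lower, Gly-GCC and Gly-CCC, and in each other list the counts adjusted over the list alone equalled those over all isoacceptors. Without Gly-CCC-5-1 the Gly-CCC log2 fold change was 0.05 (SE 0.56), so the 2 may not be separate falls. Of 4 glutamate and lysine tRNAs, Glu-CTC rose and 3 did not pass (camera adjusted p = 0.219). Of 7 isoacceptors known as main parents of long tRNA fragments in the male tract, Glu-CTC rose, Gly-GCC fell and 5 did not pass (camera adjusted p = 0.773). Of 4 tRNAs with queuosine in the anticodon, Asn-GTT fell and 3 did not pass (camera adjusted p = 0.101). Of 3 tRNAs methylated by DNMT2, Gly-GCC fell and 2 did not pass (camera adjusted p = 0.773). Among intron-containing families 1 isoacceptor was tested, Tyr-GTA, with a log2 fold change of -0.40 (SE 0.47). Its only gene counted here, Tyr-GTA-6-1, is 67 nt long and lies in an intron of Myo3a. The value may therefore not describe a tRNA that has an intron of its own.

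The third comparison asked which tRNA fragments differed, each fragment being the reads of one isoacceptor with one length and one of the 2 end classes in the deposited tables. The meaning of the end classes is not given in the sources used here. Fragment RPM come from the fragment tables and isoacceptor RPM from the tRNA gene counts, so the 2 cannot be set against each other. In wild type, Gly-GCC had 4694332 reads in the fragment tables and 2864610 in the gene counts, while His-GTG had 39519 and 74885. The main Gly-GCC fragment, 31 nt of the first class, fell from 198278 RPM to 114206 ± 1017 RPM (SD, n = 2), a log2 fold change of -0.80 (SE 0.11, edgeR adjusted p = 2.1e-10). The 50-nt Gly-GCC fragment rose with a log2 fold change of 1.59 (SE 0.34, edgeR adjusted p = 0.00048). Glu-CTC fragments of 34 nt rose from 1930 to 7314 ± 1565 RPM (SD, n = 2), a log2 fold change of 1.92 (SE 0.32, edgeR adjusted p = 1.3e-06), and those of 33 and 35 nt rose with log2 fold changes of 1.35 and 1.27. The 50-nt Gly-GCC and 35-nt Glu-CTC fragments were named after their values were seen. The Glu-CTC fragments of 31 and 30 nt had log2 fold changes of 0.56 (SE 0.19) and 0.41 (SE 0.25) and did not pass.

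Of 572 fragments tested, 13 passed an edgeR adjusted p of 0.05, with 7 higher and 6 lower. The deepest falls were those of Val-TAC at 50 nt, from 10.1 to 1.34 ± 0.0283 RPM (SD, n = 2), a log2 fold change of -2.90 (SE 0.67, edgeR adjusted p = 0.0019), and of Asn-GTT at 35 nt in the second class, with -2.72 (SE 0.57, adjusted p = 0.00034). Thr-AGT at 36 nt in the second class (-2.19), Val-CAC at 50 nt (-1.85) and Gly-CCC at 31 nt (-0.81) also fell, while Thr-TGT at 38 nt had -2.09 (SE 0.68) and did not pass. The Glu-TTC fragment of 22 nt in the second class rose from 6.95 to 49.8 ± 20.6 RPM (SD, n = 2), a log2 fold change of 2.85 (SE 0.72, edgeR adjusted p = 0.0062). Glu-TTC at 50 nt (2.71) and Ala-TGC at 53 nt in the second class (2.66) rose too, while second-class Glu-TTC fragments of 34 nt (2.16, SE 0.73) and 30 nt (2.09, SE 0.75) did not pass. Of the Gly-GCC and Gly-CCC fragments near the peak, Gly-GCC at 32 nt had -0.59 (SE 0.20), at 30 nt -0.30 (SE 0.14) and at 29 nt 0.04 (SE 0.30), and Gly-CCC at 30 nt -0.31 (SE 0.28), none past the threshold. Scaling by the sums of the fragment tables gave 14 higher and 4 lower, and DESeq2 26 higher and 6 lower. DESeq2 did not call the falls of Gly-GCC (adjusted p = 0.31) and Gly-CCC (adjusted p = 0.30) at 31 nt. Gly-CCC at 31 nt and Val-CAC at 50 nt passed in 4 of 7 settings, and Glu-TTC at 50 nt and Ala-TGC at 53 nt in 5 of 6, while Glu-CTC at 33, 34 and 35 nt, Glu-TTC at 22 nt and Gly-GCC at 50 nt passed in 7 of 7 settings.

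The fourth comparison asked whether the lengths of tRNA fragments differed. Fragments of 30 to 33 nt made up 90.7% of the fragment reads in wild type and 84.2% ± 0.0839 (SD, n = 2) in Alkbh3-/-. Those of 34 to 36 nt made up 3.46% in wild type and 6.94% ± 0.585 (SD, n = 2), and those of exactly 50 nt 0.497% and 1.55% ± 0.0987 (SD, n = 2). Glu-CTC supplied 76674 of the 223044 wild type reads of 34 to 36 nt, 246637 of 389317 in library A and 277523 of 496330 in library B. The pooled shares therefore also reflect the mix of isoacceptors. Of 24 with 1000 or more fragment reads in each library, the 30 to 33 nt share was lower in both Alkbh3-/- libraries in 10, Gly-GCC and Glu-CTC among them, and higher in both in 7, such as Met-CAT (49.3% against 58.9% and 57.0%) and Gly-TCC (49.04% against 55.9% and 56.1%). The 34 to 36 nt share was higher in both in 15 of the 24 and lower in both in 4. The median fold of 34 to 36 nt reads per read of 30 to 33 nt over 25 isoacceptors was 1.23 in library A (95% resampling interval 0.980 to 1.41) and 1.12 in library B (0.979 to 1.24), both intervals including 1. Within Glu-CTC the share of 33-nt reads was 15.7% in wild type against 25.7% in library A and 19.4% in library B, and that of 34-nt reads 3.88% against 9.76% and 6.77%. Within Gly-GCC the share of 31-nt reads was 63.8% against 55.5% and 52.7%, and that of 50-nt reads 0.555% against 2.59% and 2.34%. The other lengths above 36 nt together held 0.127% of the Gly-GCC reads against 0.400% and 0.509%. The second end class held 0.377% of the fragment reads in wild type, 0.414% in library A and 0.418% in library B.

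For the 30 to 33 nt share the gap between genotypes exceeded that between the Alkbh3-/- libraries, at 84.22% and 84.10%, and no test was made on it, since an exact permutation test of 1 library against 2 cannot give a p below 0.33. The 30 to 33 nt range was chosen after the lengths were seen. With each distinct fragment weighted once in place of its reads, the difference was -0.661 percentage points in place of -6.54.

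**Figure D3:**
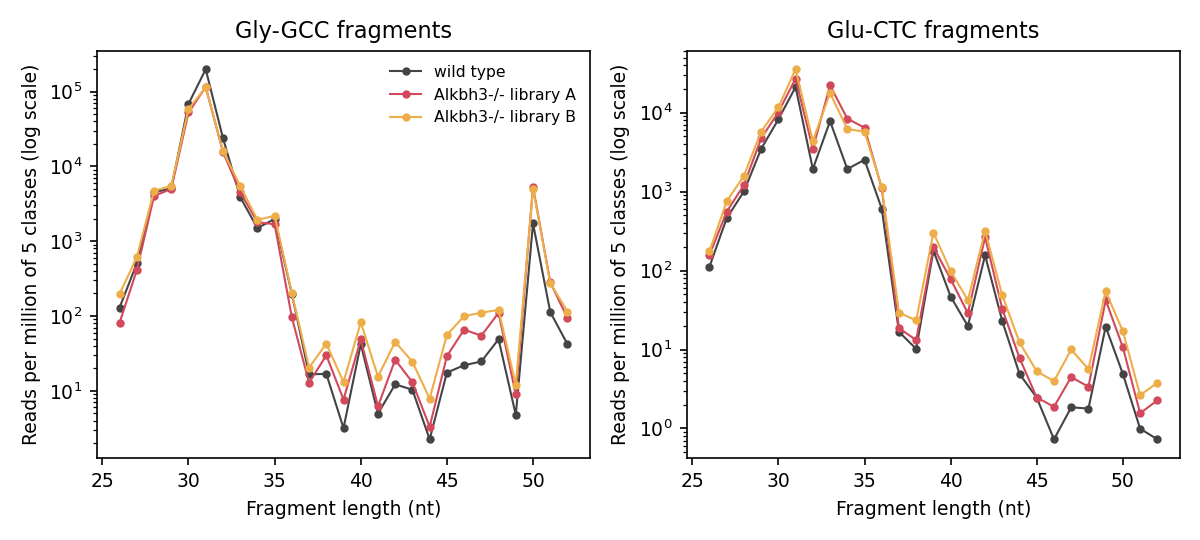
RPM of the 5 classes (log axis) by fragment length in nt for Gly-GCC and Glu-CTC, 1 line per library. Wild type lies above both Alkbh3-/- libraries at 31 nt in Gly-GCC and below both at 50 nt, and below both at 33 and 34 nt in Glu-CTC.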

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

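The alternatives without miRNA or rRNA, other tables for the tRNA share, edgeR's older method, the fragment tables as a source or with their own sums and the removal of Gly-CCC-5-1 and Asn-GTT-3-2 were chosen after seeing the data. The tRNA share differed between genotypes by -7.42 percentage points, by -0.877 without miRNA in the total, -13.1 without rRNA, and -4.48 from the tRNA gene counts, since the total or the table changed. Leaving out 1 Alkbh3-/- library gave -8.22 to -6.62 points, and for the 30 to 33 nt share -6.60 to -6.48. That share moved to -0.661 points with distinct fragments in place of reads. Of 46 isoacceptors tested, 11 were called, against 3 with DESeq2 (2 among the 11), 5 with edgeR's older method and 5 without the 2 gene copies (5 among the 11 in each), while 36 single genes passed. Of 572 fragments tested, 13 were called, against 48 with TMM (all 13 among them) and 32 with DESeq2 (11 of the 13 among them). With an estimated correlation, tested on 1 degree of freedom, 0 lists passed in place of 1. The leucine and serine list also passed with TMM (camera adjusted p = 0.00029). Direction changed for Asp-GTC (0.081 with TMM, 0.18 with tRNA sums, 0.23 with DESeq2), Lys-CTT (0.10 with tRNA sums, 0.20 with DESeq2), Val-AAC (0.0058 and 0.026 likewise) and Gly-CCC (0.055 without Gly-CCC-5-1). The cause was not tested beyond these settings. Across the other settings of named isoacceptors 111 values kept direction and side of the threshold, 20 lost the call and 5 gained it, and for fragments 94, 9 and 9. Leaving out 1 Alkbh3-/- library moved 36 of 36 isoacceptor values and 38 of 40 fragment values by less than the SE, the exceptions being Asn-GTT at 35 nt (-3.48) and Glu-CTC at 31 nt (0.35), both without library B. The SE comes from the spread of the same 2 Alkbh3-/- libraries, and every value still rests on the same wild type library. Small moves are therefore no sign of stability. With 1 library left out no residual degree of freedom remained, so only values were compared. Another library total was not run, since the class table used here gives none. No paired analysis was possible because the wild type library has no replicate number and the columns carry none. In the simulations 46.7% of 2-fold isoacceptor changes and 10.5% of 2-fold fragment changes were recovered, so changes of this size can be missed. Depth was not varied.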

Other observations

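Fragments of 50 nt moved in opposite directions in different tRNAs. Of 11 isoacceptors other than Gly-GCC with 100 or more 50-nt reads, the 50-nt share of the isoacceptor's own reads was lower in both Alkbh3-/- libraries in 7 and higher in both in 3 (Glu-CTC, Glu-TTC and Gly-CCC). In Gly-TCC it was 20.2% in wild type against 6.89% in library A and 7.43% in library B, and in Val-TAC 4.74% against 1.29% and 0.978%. In Glu-TTC it was 0.0764% against 0.328% and 0.387%. Gly-GCC supplied 81.2% of all 50-nt reads in wild type, 96.3% in library A and 94.8% in library B. Short reads of 16 to 24 nt made up 0.976% of Glu-TTC reads in wild type and 2.32% and 3.02% in the Alkbh3-/- libraries. These tRNAs were chosen after their values were seen, and none of these shares was tested.

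Of the tests in the next 3 paragraphs, all but that of a peculiarity of the wild type library were chosen after the values they bear on had been seen in part or in full. Whether a gel excision shifted towards shorter RNA could account for the higher miRNA share and the lower tRNA share in both Alkbh3-/- libraries stays open. For it, within 11 isoacceptors, reads of 16 to 24 nt per read of 30 to 33 nt had a median fold over wild type of 1.38 in library A (95% resampling interval 1.02 to 2.28) and 1.83 in library B (1.47 to 2.63), against 2.02 and 2.39 for miRNA per tRNA read, though Glu-CTC had folds of 0.422 and 0.793. Against it, longer fragments also took a larger share of all fragment reads, 3.46% against 7.36% and 6.53% at 34 to 36 nt and 0.554% against 0.676% and 0.830% at 37 to 49 nt. These pooled shares also reflect the mix of tRNAs, since Glu-CTC supplied 76674 of 223044 wild type reads at 34 to 36 nt, 246637 of 389317 in library A and 277523 of 496330 in library B. Within isoacceptors the median folds per read of 30 to 33 nt were 1.23 (0.980 to 1.41) and 1.12 (0.979 to 1.24) at 34 to 36 nt. Above 36 nt they were 0.907 (0.776 to 1.24) and 0.938 (0.617 to 1.16), and every interval included 1. Without miRNA in the total, the tRNA share was lower than the wild type 52.6% in library A (48.5%) and higher in library B (55.0%), so the miRNA rise alone is left open as the source of the lower tRNA share. A peculiarity of the wild type library, a difference in genetic background between the groups and an effect of genotype cannot be told apart with 1 wild type library, and all stay open.

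Gly-CCC was lower in both Alkbh3-/- libraries, at log2 ratios of -0.64 and -0.59. A candidate explanation is reads shared with Gly-GCC, since Gly-CCC-5-1 held 97.7%, 96.8% and 95.8% of the Gly-CCC reads in the 3 libraries. The other 6 Gly-CCC genes had log2 ratios of -0.18 in library A and 0.25 in library B, which is consistent with this. A fall of Gly-CCC-5-1 itself stays open, because the tables hold no sequences.

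The higher 50-nt share of Gly-GCC may reflect a change in the long fragments of this tRNA, as a hypothesis found and tested on the same data. It was not particular to 50 nt, since the mean Alkbh3-/- share was 4.44 times the wild type share at 50 nt, 3.45 times at 37 to 49 nt and 3.74 times at 51 nt or more. A library-wide excess of 50-nt reads is argued against by the 7 of 11 other isoacceptors whose 50-nt share was lower in both Alkbh3-/- libraries. A gain of fragments above 36 nt in most tRNAs is argued against. Of 23 other abundant isoacceptors, 2 had a higher share above 36 nt, without 50 nt, in both. By length, among 24 isoacceptors with Gly-GCC included, the 37 to 49 nt share was higher in both in 7 and lower in both in 10. At 51 nt or more it was higher in both in 10 and lower in both in 10. The rise was not particular to Gly-GCC. In Glu-TTC the mean Alkbh3-/- share was 4.68 times the wild type share at 50 nt and 4.72 times at 51 nt or more, but 0.923 times at 37 to 49 nt. Reads that Gly-GCC shares with other sequences, the single wild type library and the genotype stay open and were not tested.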
